A study of Arabidopsis thaliana with 3 samples.

How the data were processed

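Ribosome footprints were sequenced from 4-week-old leaves of Arabidopsis thaliana Col-0 plants carrying the 35S:RUBY transgene, in 3 libraries from 3 transgenic events. Per the labels, events MK016 and MK045 were Always Red and event MK040 was Fully Red. The libraries are named always red 1 (MK016), always red 2 (MK045) and fully red 1 (MK040). The replicate numbers of the always red libraries follow the order of deposit and pair nothing. Per the labels' protocols, plants grew in soil at 22 °C with 18 h of light and 6 h of dark, RNase I treatment of leaf extracts lasted 1 h, monosomes were recovered by size exclusion, footprints of 25 to 33 nt were selected on a gel, and libraries were made with a SMARTer small RNA kit. The labels mention no molecular identifiers, so repeated reads could not be told from separate molecules.

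The authors deposited, per the file headers, 1 line for each aligned read and transcript, with the 5′ end, the P-site, the 3′ end, the read length, the bounds of the coding sequence and the region of the P-site. These values are positions and lengths in nt on a transcript, so no column of the deposited files holds a count, a signal or a score. Per the submitters' processing notes, cutadapt, Bowtie2 2.5.2, STAR and the TAIR10 build were used, with no roles given. The tool that placed the P-sites is not given in the sources used here. Reads of 31 to 34 nt are present in all 3 libraries. In the deposited lines the P-site lies 13 nt after the 5′ end, and 14 nt after it for the 34-nt reads of fully red 1, which moves those reads by 1 nt in frame relative to the other libraries. A read can appear on every transcript of a gene. The transgene is 1 extra transcript named RUBY, with a coding sequence of 3957 nt from position 17 to position 3973.

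Lines were tallied here with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. For each gene the transcript with most coding P-sites over all libraries was used, with ties going to the lowest transcript number. The 19410 gene identifiers were all found in the TAIR10.1 RefSeq gene table, which was used for symbols only, and 8572 of them have a symbol other than the identifier. Chloroplast and mitochondrial identifiers (ATCG and ATMG) were not seen among the lines. Because the files hold no counts column, the test was limma-voom (limma 3.58.1, R 4.3.3) on tallied lines, as foreseen for this case before the data were examined. Scaling used trimmed means of M values. Genes needed 10 or more P-sites in at least 1 library and 30 or more in total, which left 11314 genes with the transgene among them. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are fully red minus always red. The single fully red library was assumed to vary like the always red ones, and the fit had 1 residual degree of freedom per gene. Gene p-values measure only the spread between these samples, and mostly that spread as pooled over genes. The pooled part carried 39.8 prior degrees of freedom, against the 1 of the gene itself. They therefore say little about a gene's own variation between libraries. No permutation of 2 libraries against 1 can give a p below 0.333. Levels are scaled to 1000000 coding P-sites. A gene at 0 in a group was given a floor of 3 P-sites per library. Its fold at that floor is a lower bound only for independent reads, not for repeated ones. Intervals are 95% exact binomial or Poisson intervals and, like the floors, cover counting error of independent reads only. Repeated reads make those on all reads too narrow, most of all in fully red 1.

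The fit was tested on simulated data for the fully red against always red comparison. In a simulation of 10950 genes, 91 of 100 genes changed 4-fold and 99 of 100 changed 8-fold were recovered, and 13 unchanged genes were called. The simulation drew independent reads, without the repeats seen in the real libraries.

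Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. At the preset correlation the list p treats genes as replicates and does not measure variation between plants. With an estimated correlation it rests on the 1 residual degree of freedom of the fit. The estimate for the ribosomal protein list was -0.016, below the preset, so a higher estimate does not account for the change in its p. For the jasmonate list it was 0.56 and for nuclear photosynthesis 0.9. With 1 residual degree of freedom no such estimate can show how far the genes of a list vary together. List medians were also placed among 10000 random lists of the same size matched on mean level. Fixed before the data were examined were 21 lists with 372 entries, and a list of cytosolic ribosomal proteins was to be taken from the gene table. The words that select that list (symbols or synonyms of 40S, 60S or cytoplasmic ribosomal proteins or of the RPL and RPS families) were chosen after the data were seen. They gave 33 genes, fewer than the whole family. The 6 trans-acting siRNA precursors had no tallied line and were not analysed here, and 1 meristem marker passed the filter, so neither was tested as a list.

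Named genes follow a rule fixed before the data were examined. It takes the transgene, up to 10 rising and 10 falling genes with the largest log2 fold change among those past the threshold, beyond both always red values and at 5 or more P-sites per 1000000 coding P-sites. It also takes up to 4 members of each list beyond both always red values, the 5 genes with most coding P-sites, and the SAMDC1, bZIP11, SAC51 and VTC2 genes with upstream reading frames. RPL18AA, VSP1, MT3 and AT1G72645 were added after their values were seen. RUBY P-sites were divided over 10 equal parts of the coding sequence, and distributions were compared by total variation distance, the percentage of P-sites that would have to move. Codons were compared with the mean of the coding sequence, leaving out the first 15 and last 5 codons. The reading frame with most P-sites was read without AT3G20362.

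The alternatives covered scaling, transcript choice, coding ends, read length, filters, the test, the reading frame and each always red library in turn. Counting each position and length as 1 footprint was planned for the RUBY distribution. It was added for the other results after the data were seen, as was leaving out genes with most P-sites at a single position. Such a count is capped by the positions and read lengths available, so it flattens deeply covered genes and high positions. Figures were drawn with matplotlib 3.10.9, and intervals came from scipy 1.17.1.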

Results

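RUBY is a red reporter. Its single reading frame encodes CYP76AD1, DOPA dioxygenase and a glucosyltransferase joined by 2A peptides, which make betalain from tyrosine. The series concerns an aberrant RNA at the start of transgene silencing. The ribosome profiling part asked where ribosomes lay, and on which RNAs, in leaves of events that were always red or fully red. There were 2 always red libraries and 1 fully red library, each from another transgenic event, so event and phenotype cannot be told apart and no fully red value has a replicate. The files held 2655653 lines for always red 1, 1950761 for always red 2 and 5015915 for fully red 1.

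On 1 transcript per gene, coding P-sites numbered 1456237, 1088445 and 3404815 in the same order. The fully red library held fewer separate footprints than either always red library. AT3G20362, a short reading frame of 144 nt, took 50.7% of the coding P-sites of fully red 1, against 12.5% in always red 1 and 12.7% in always red 2. A single 5′ end at position 110 of its transcript held 64.8%, 68.0% and 80.6% of that gene's P-sites in always red 1, always red 2 and fully red 1. They lay on 119, 108 and 84 distinct footprints, and whether these reads came from ribosomes was not tested. Without that gene, distinct combinations of position and read length numbered 807053 in always red 1, 597491 in always red 2 and 339147 in fully red 1. Repeats made up 36.7%, 37.1% and 79.8% of the remaining P-sites, with means of 1.58, 1.59 and 4.95 lines per distinct footprint. Frame 0 held 42.2% and 41.9% of coding P-sites in the always red libraries and 37.5% in fully red 1, again without AT3G20362. With that gene counted, the shares were 39.2%, 38.6% and 26.1%. Across 11314 genes, which are not independent replicates, the Spearman correlation of P-sites was 0.87 between the always red libraries and 0.70 between fully red 1 and each of them.

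**Figure D1:**
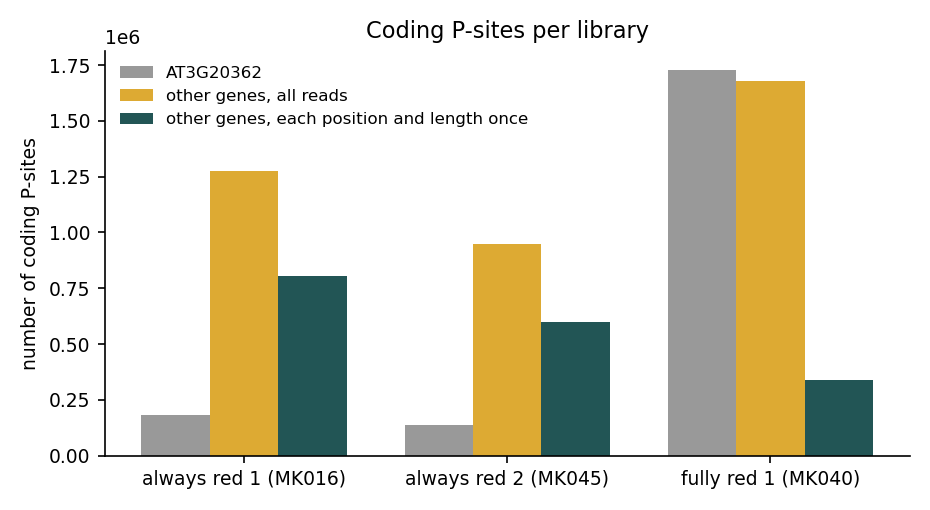
Number of coding P-sites (vertical axis) for each of the 3 libraries. Grey bars show AT3G20362, yellow bars all reads on other genes and dark bars other genes with each position and read length counted once; fully red 1 has the most reads and, at 339147, the fewest distinct footprints.

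The RUBY transgene carried many footprints in all 3 events, and a difference in its level was not detectable. It held 44919 coding P-sites in always red 1, 19358 in always red 2 and 77806 in fully red 1. Scaled to 1000000 coding P-sites this was 30846 (95% Poisson interval 30561 to 31133), 17785 (17535 to 18037) and 22852 (22691 to 23013). Without AT3G20362 in the total, the values were 35238, 20376 and 46387 on the same scale. The log2 fold change of fully red over always red was 0.90 ± 1.14 (SE), with an adjusted p of 0.63 in limma-voom. Against always red 1 alone it was 0.63 and against always red 2 alone 1.14. With no scaling beyond total coding P-sites it was -0.045 (adjusted p 0.97).

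The distribution of P-sites along RUBY differed between fully red 1 and both always red libraries by more than these differed from each other. When the coding sequence was divided into 10 equal parts, part 7, positions 2393 to 2788 of the transgene transcript, held 17.8% of RUBY P-sites in fully red 1 (95% exact interval 17.5% to 18.0%), against 11.3% and 10.7%. Part 10, positions 3581 to 3973, held 3.99% (3.86% to 4.13%), against 8.35% and 7.66%. Part 3, positions 809 to 1204, held 13.9% against 10.3% and 10.7%. With each position and length counted once it held 10.2% against 9.83% and 10.3%. That count cannot show height at a position, and codons 363 and 364 in part 3 held 1110 and 1363 P-sites in fully red 1. Counted that way, part 7 held 13.8% against 10.8% and 10.8%, and part 10 held 5.12% against 8.17% and 7.58%. This part 10 share was 0.65 times the always red mean. Among 190 other deeply covered genes the median of that ratio was 0.94, and 27.4% of them had a lower ratio than RUBY. A fall of that size in the last part was thus not particular to RUBY. The total variation distance of fully red 1 was 12.0 percentage points from always red 1 and 11.7 from always red 2, against 2.43 between the always red libraries. With each position and length counted once, these distances were 6.27, 5.41 and 2.3.

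**Figure D2:**
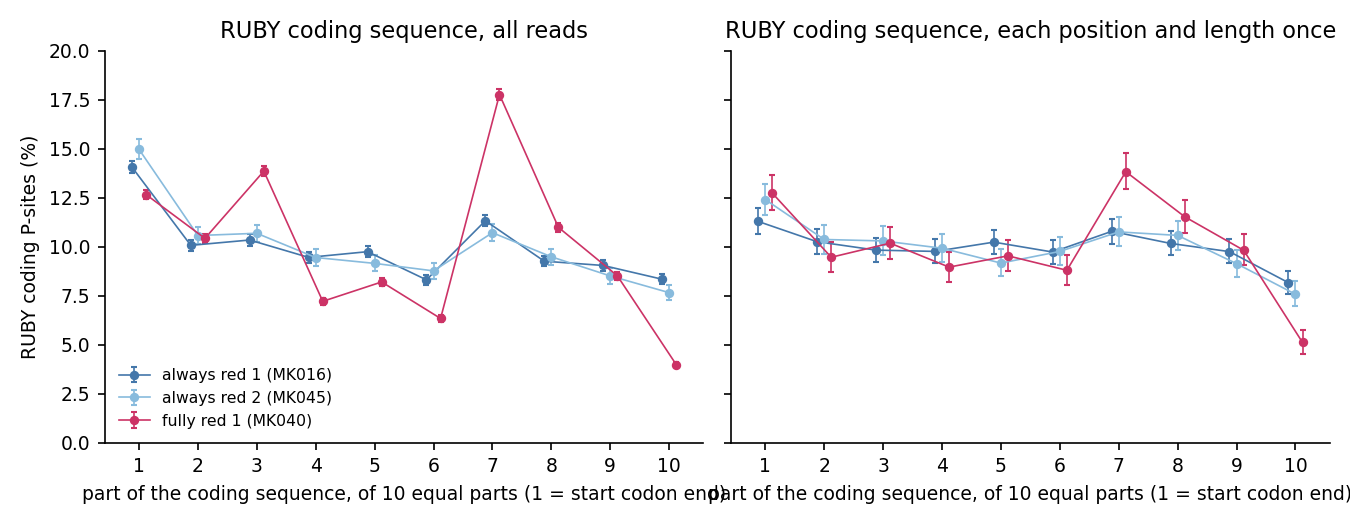
Percentage of RUBY coding P-sites (vertical axis) in each of 10 equal parts of the coding sequence from the start codon (horizontal axis), for all reads (left) and with each position and read length counted once (right). Points are single libraries and bars are 95% exact binomial intervals; fully red 1 stands above the always red libraries in part 7 (17.8%, or 13.8% on the right) and below them in part 10.

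Within RUBY, fully red 1 had 9 codons at 10 or more times the mean, and the always red libraries had 0. Among 32-nt reads alone the counts were 4 and 3 in the always red libraries and 12 in fully red 1, and at 5 or more times the mean, over all reads, 8, 8 and 47. The highest was codon 364, at 22.9 times the mean against 7.01 and 7.88, followed by codon 881, at 20.7 times against 2.66 and 2.33. With each position and length counted once no codon could reach 10 times the mean, since a codon offers few combinations of position and length. That count therefore cannot test these codons. The 77806 RUBY P-sites of fully red 1 lay on 5567 distinct footprints, against 44919 on 9094 in always red 1 and 19358 on 6729 in always red 2. Repeats on RUBY were thus most frequent in fully red 1, and whether they account for its high codons was not tested. Across 1299 codons, which are not replicates, the Spearman correlation was 0.80 between the always red libraries, 0.56 between fully red 1 and always red 1, and 0.44 between fully red 1 and always red 2. Frame 0 held 46.6% and 46.5% of RUBY P-sites in the always red libraries and 35.3% in fully red 1, where frame 1 held 38.3% and frame 2 26.4%. The frames were thus more even in fully red 1, and whether all its RUBY reads came from ribosomes was not tested. Among 32-nt reads alone, frame 0 led in fully red 1 with 42.2%. P-sites in the 5′ untranslated region of RUBY numbered 87 and 60 in the always red libraries and 8 in fully red 1, or 0.193%, 0.308% and 0.010% of RUBY P-sites. By distinct footprints they were 11, 9 and 1. The interval of fully red 1 (0.00045% to 0.0996%) then overlapped those of always red 1 (0.060% to 0.215%) and always red 2 (0.061% to 0.252%). The RUBY coding sequence starts at position 17 of its transcript. Given the distance from the 5′ end to the P-site, only the few positions next to the start codon could hold such a P-site. That distance also differed for the 34-nt reads of fully red 1. These counts and shares therefore cannot compare upstream ribosomes on RUBY between libraries.

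Of the gene lists tested, jasmonate and senescence genes had the highest medians in fully red 1 and ribosomal protein genes the lowest. In limma-voom, 880 of 11314 genes were higher and 559 lower in fully red 1 than in the always red libraries, with 3243 at an unadjusted p under 0.05. The counts depended on the filter on low counts. Among the 5909 genes with 100 or more P-sites none passed the threshold (1709 at an unadjusted p under 0.05, smallest adjusted p 0.068), and the prior degrees of freedom of the fit were 5.31 there against 39.8. With each position and length counted once, 611 genes were higher and 73 lower, of which 551 and 72 were also among the calls above. With no scaling beyond total coding P-sites, 207 genes were higher and 2820 lower, and the median of all genes moved by -0.95 on the log2 scale, so directions below are relative to the scaled median.

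Where leaving out a library moved a fold by more than 1.5 times, the log2 values against always red 1 and always red 2 follow in brackets. By fitted fold change, the 10 genes that rose most included JAZ7, ranked over zero counts, and 2 enzymes that act on jasmonate. JAZ7 (AT2G34600), a repressor of jasmonate signalling, and AT1G62760 had no P-sites in either always red library and 54 and 109 in fully red 1. At the floor of 3 P-sites they were 12.2-fold and 24.7-fold higher. Their reads lay on 11 and 43 distinct footprints, and JAZ7 could not be tested by distinct footprints. CYP94B3 (AT3G48520) and CYP94C1 (AT2G27690), which oxidise the active jasmonate, were 39.7-fold [5.99, 4.15] and 31.9-fold [5.41, 4.22] higher, with SE of 0.94 and 0.64 on the log2 scale. PLA2A (AT2G26560), a lipid acyl hydrolase, rose by 4.79 ± 0.67 [5.73, 3.53], and its adjusted p was 1.35e-05. FAMT (AT3G44860), a methyltransferase, rose by 4.89 [6.14, 2.63], AT4G22470 by 4.95 [3.78, 7.05] and AT4G16260, with 10 and 0 P-sites in the always red libraries, by 5.60 [4.04, 7.74]. AT1G73810 had 1 P-site in the always red libraries together and AT5G39520 had 3 [4.06, 6.17]. Their ratios were 77.7 (95% counting interval 13.4 to 3126) and 31.2 (10.2 to 155).

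By fitted fold change, the 10 genes that fell most had no P-sites in fully red 1, so their ranking rests on zero counts. These genes included AT3G22210, AT3G51270, AT5G21060, the asparaginyl-tRNA synthetase NS2 (AT3G07420) and the wax ester synthase WSD1 (AT5G37300). WSD1 had 63 and 7 P-sites in the always red libraries [-7.16, -4.77]. The others were AT1G79620, AT3G26370, 3xHMG-box2 (AT4G23800), AT5G56940 and AT2G44140. At the floor of 3 P-sites the folds of all 10 were 9.87-fold to 14.8-fold lower, with adjusted p from 0.0084 to 0.030 in limma-voom. In fully red 1 a distinct footprint held 4.95 lines on average, above that floor, so these are not firm lower bounds. With each position and length counted once, AT3G22210, AT3G51270 and NS2 remained past the threshold among these 10.

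Jasmonate synthesis and response was higher as a list, with a median log2 fold change of 2.16 and an adjusted camera p of 5.04e-07, which was 0.89 with an estimated inter-gene correlation. Of 17 members tested, 10 rose and 1 fell over all genes tested, and 11 rose and 2 fell adjusted over the list alone. Besides JAZ7, LOX4 (AT1G72520) and LOX3 (AT1G17420), lipoxygenases of the pathway, rose by 4.38 ± 0.58 [4.80, 3.59] and 4.04 ± 0.54 [4.65, 3.13], and JAZ10 (AT5G13220) rose with an adjusted p of 0.0091. VSP1 (AT5G24780), a vegetative storage protein, fell by 3.42 on the log2 scale [-2.21, -4.58]. Senescence and dark induction was higher (median 1.34, adjusted p 2.74e-07, or 0.89 with an estimated correlation), with all 15 members above 0. Of these, 6 rose and 0 fell, or 9 and 0 adjusted over the list alone. They included DIN2 (AT3G60140), a beta-glucosidase, at 4.09 ± 1.25 [2.85, 5.32], BCAT-2 (AT1G10070), an aminotransferase of branched-chain amino acids, at 3.58 ± 0.62, SAG21 (AT4G02380) at 3.03 [2.40, 3.89] and BCB (AT5G20230) at 2.75 [3.403, 1.916]. Salicylic acid and defence was higher (median 0.78, or 0.89 against always red 1 and 0.46 against always red 2; adjusted p 0.014, or 0.89 with an estimated correlation), with 5 of 18 members up and 0 down, or 6 and 0 adjusted over the list alone. The transcription factors WRKY18 (AT4G31800) and WRKY33 (AT2G38470) rose by 3.81 ± 0.60 and 3.74 ± 0.50, the receptor-like protein RLP23 (AT2G32680) by 2.39 and the glucanase BGL2 (AT3G57260) by 2.00. Counted by distinct footprints, these 3 lists had medians of 1.44, 1.23 and 0.74 and adjusted p of 8.83e-08, 4.66e-08 and 0.00027.

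Cytosolic ribosomal protein genes, chosen by words set after the data were seen, were lower as a list, with a median log2 fold change of -1.57 and an adjusted camera p of 1.64e-14, which was 0.89 with an estimated correlation. Of 28 tested, 21 fell and 1 rose over all genes, and 24 fell and 1 rose adjusted over the list alone. AT4G14320, PFL (AT1G22780), RPS5B (AT2G37270) and AT3G23390 fell by 3.46, 3.10, 3.02 and 2.53 on the log2 scale, and RPL18AA (AT1G29970) rose by 1.54 [0.92, 2.41]. None of these 5 passed by distinct footprints. Counted that way, 4 other members of 28 passed, all lower, and the list had a median of -1.33 and an adjusted p of 2.44e-11. Nuclear photosynthesis genes were lower as a list (median -0.66, adjusted p 0.017, or 0.89 with an estimated correlation), with 0 of 40 members past the threshold and 0 adjusted over the list alone. The median was -0.21 against always red 1, -1.02 against always red 2 and -0.24 by distinct footprints. Among them CAB2 (AT1G29920), a chlorophyll-binding protein, stood at -1.73 ± 0.68 [-1.05, -2.29] and GAPB (AT1G42970) at -1.49 ± 0.53. This list had an adjusted p of 0.062 by distinct footprints.

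**Figure D3:**
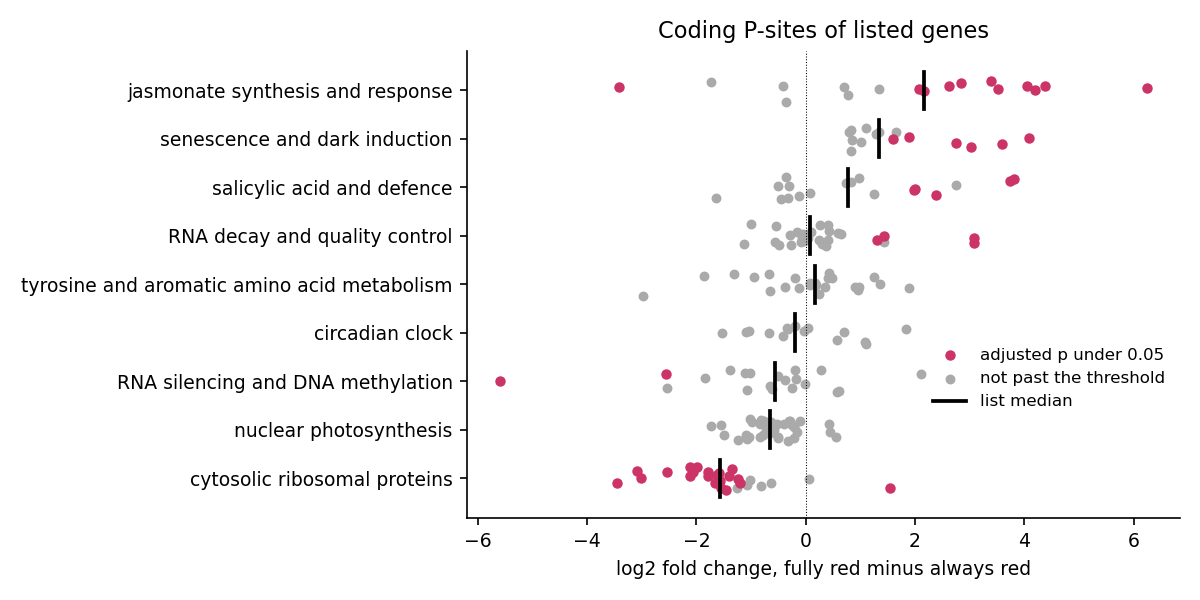
Log2 fold change of coding P-sites, fully red minus always red (horizontal axis), for members of 9 gene lists (vertical axis). Each point is a gene, red where the adjusted p was under 0.05 and grey otherwise, and black bars are list medians, from 2.16 for jasmonate to -1.57 for ribosomal proteins; points are jittered vertically.

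Genes of RNA silencing and DNA methylation had a median log2 fold change of -0.56 with an adjusted list p of 0.126. Of 20 members, 0 rose and 2 fell, the same counts adjusted over the list alone. AGO4 (AT2G27040), the Argonaute of RNA-directed DNA methylation, fell by 2.55 ± 0.74 (SE). HEN1 (AT4G20910), the methyltransferase that protects small RNAs, had 22 and 12 P-sites in the always red libraries and 0 in fully red 1. At the floor of 3 P-sites HEN1 was 7.76-fold lower, which is no firm lower bound given the repeated reads. Neither passed when each position and length was counted once (adjusted p 0.38 and 0.10). In RNA decay and quality control, 4 of 30 members rose and 0 fell, with 4 and 0 adjusted over the list alone, a median of 0.07 and an adjusted list p of 0.395. They were the deadenylases CAF1a (AT3G44260) at 3.08 ± 0.54 and CAF1b (AT5G22250) at 3.07 ± 0.82, the uridylyltransferase AT2G45620 at 1.44 and the decapping protein DCP1 (AT1G08370), whose adjusted p was 0.037. By distinct footprints CAF1a and AT2G45620 passed, DCP1 did not (adjusted p 0.12) and CAF1b could not be tested. None of the 24 tested genes of tyrosine and aromatic amino acid metabolism, which supplies the pigment precursor, passed the threshold, over all genes or adjusted over the list alone (median 0.17, adjusted list p 0.656).

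Among the other lists, abscisic acid, cold and dehydration had 3 of 17 members up, with the dehydrins ERD10 (AT1G20450) at 2.27 and COR47 (AT1G20440) at 1.65. Glucosinolate synthesis had 2 of 19 down, IMD1 (AT5G14200) at -2.84 [-2.18, -3.46] and AT2G31790 at -2.13. Single members passed in 4 further lists. They were the regulator MYBL2 (AT1G71030) at 1.51 [2.28, 0.77] of 13 phenylpropanoid and anthocyanin genes, the acid phosphatase PAP17 (AT3G17790) at 1.85 [0.98, 3.41] of 4 phosphate starvation genes, the chaperone BIP1 (AT5G28540) at -1.22 of 5 heat shock and folding genes, and the lipid transfer protein LP1 (AT2G38540) at -1.79 [-2.39, -1.31] of 7 epidermal markers. Adjusted over the list alone, 4 abscisic acid genes were higher, 2 glucosinolate genes lower, PAP17 higher, BIP1 and LP1 lower and MYBL2 not past the threshold. By distinct footprints ERD10 and IMD1 remained past the threshold over all genes, and COR47, AT2G31790, MYBL2, PAP17, BIP1 and LP1 did not. The circadian clock, with 15 genes, the 8 tested genes with conserved upstream reading frames, and the guard cell, phloem, xylem and flowering markers had 0 members past the threshold. By distinct footprints 1 clock gene was higher (adjusted p 0.036), and none passed in the others. Adjusted over the list alone, 1 gene with an upstream frame was higher and 2 were lower, and none passed in the clock or marker lists without calls. Adjusted list p lay between 0.146 and 0.953 for all the lists from abscisic acid to flowering, and no list of tissue markers passed as a list.

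Of the 5 genes with most coding P-sites, none passed the test. Besides RUBY these were AT3G20362 (log2 fold change 2.92, adjusted p 0.16), AT2G07732 (-0.84), the Rubisco small subunit RBCS1A (AT1G67090, -0.98) and the catalase CAT3 (AT1G20620, 1.69). AT2G07732 turned to 0.53 when each position and length was counted once.

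Footprints upstream of coding sequences took a larger share in fully red 1 when AT3G20362 was set aside. The 5′ untranslated share was then 3.96% (95% exact interval 3.93% to 3.99%) in always red 1, 3.81% (3.78% to 3.85%) in always red 2 and 7.36% (7.32% to 7.39%) in fully red 1. With AT3G20362 in the total the shares were 3.51%, 3.37% and 3.86%, and by distinct footprints 3.86%, 3.80% and 6.27%. The 3′ untranslated shares were 5.04%, 5.09% and 2.37%, or 5.69%, 5.76% and 4.51% without AT3G20362. By distinct footprints they were 2.57% (2.53% to 2.60%), 2.04% (2.01% to 2.08%) and 1.97% (1.93% to 2.02%), so the intervals of always red 2 and fully red 1 overlapped. Of single genes, SAMDC1 (AT3G02470), whose upstream frame represses the polyamine enzyme, had 56.4% (53.9% to 58.9%), 64.1% (60.5% to 67.5%) and 73.1% of its 5′ and coding P-sites upstream, and the intervals of the always red libraries did not overlap either. VTC2 (AT4G26850) had 42.8%, 52.3% (36.7% to 67.5%) and 65.8%, so fully red 1 lay within the interval of always red 2. By distinct footprints SAMDC1 had 330, 254 and 182 upstream and 437, 211 and 142 in the coding sequence, and VTC2 had 82, 20 and 11 upstream and 132, 19 and 7 in the coding sequence. BZIP11 (AT4G34590) and SAC51 (AT5G64340) had at most 27 upstream P-sites in a library, too few to separate the libraries. The trans-acting siRNA precursors TAS1A, TAS1B, TAS1C, TAS2, TAS3 and TAS4 were not analysed here, since no line was tallied for them.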

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

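The time-of-day test, the test of an average shift on RUBY and the test on 5′ untranslated footprints were chosen only after the results were seen. Some lines lay on transcripts without a coding sequence, outside every comparison above. They numbered 264 in always red 1, 196 in always red 2 and 418 in fully red 1, above the 3 that a count of 0 allows, on 10, 9 and 9 transcripts. Counted by distinct positions and lengths they were 229, 173 and 103.

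The genes and lists that separated fully red 1 from the always red libraries were weighed against its few distinct footprints. Of 20 libraries simulated from the always red means with 339147 distinct footprints and the observed repeats, the median gave 131 calls (59 to 170) against 1439, the highest jasmonate median was 0.48 against 2.16, and the lowest ribosomal protein median was -0.35 against -1.57. This argues against few footprints as the whole cause, although 131 calls with no effect show that many single genes may be chance. Harvest at another time of day was argued against for the jasmonate list, since its median was 1.92 against MK045 alone, whose 15 clock genes lay 0.36 (median absolute log2 difference) from fully red 1 against 1.29 for MK016. Wounding or handling of the plants, the event and the phenotype were not tested and stay open, since the design holds 1 fully red library.

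The RUBY footprint distribution was weighed against sampling and against a property of the whole library. In 1000 draws of 5567 distinct footprints from the always red positions, the largest distance was 7.47 percentage points against 11.8 observed, which argues against few footprints as the whole cause. At 200 distinct footprints per gene, RUBY was compared with 190 other genes with at least 100 codons. Its distance from the always red mean (11.5) lay at their 6.32 percentile, below their median of 18.0. At that depth RUBY therefore moved less than most of these genes. Between the always red libraries the distance was 11.8 for RUBY, and the median of the other genes was 11.3. Being between single libraries, these are not directly comparable with distances from a mean. The excess over the distance between the always red libraries was 1.07 for RUBY, against a median of 7.57. A positional difference shared by other transcripts is thus not argued against. With so small an excess, the test cannot tell whether it accounts for the RUBY difference. When the always red RUBY profile was shifted along the 10 parts as other genes were on average in fully red 1, the distance by distinct footprints rose from 5.60 to 9.12, against at most 3.94 in 1000 draws from the shifted profile. This argues against that average shift, taken by equal parts, as the cause. A shift set in codons from the start codon was not tested, since equal parts differ in length between genes. A positional difference that depends on the sequence of each transcript was not tested and stays open. A biological difference between the events stays open and untested.

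The higher 5′ untranslated share of fully red 1 was tested against a few transcripts with high counts at single positions. After the 20 transcripts with most 5′ P-sites were left out and each position and length counted once, the share was 6.04% against 3.68% and 3.60%, still 1.64 times the higher always red share. This argues against those transcripts as the cause. Other library differences and the event could account for it and were not tested.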

How the results depend on the processing

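Counting each position and length once (except for the RUBY distribution) and leaving out AT3G20362 or AT1G72645 were chosen after the data were seen. The counts of 880 higher and 559 lower genes became 207 and 2820 with total coding P-sites only, 349 and 141 with all transcripts summed, 202 and 113 with 1 read length, 383 and 217 in the main frame, and 0 and 0 among genes with 100 or more P-sites, where the prior degrees of freedom were 5.31. Higher genes became 500 with limma-trend. Lower genes became 363 with median-of-ratios factors, 73 with each position and length counted once and 361 with AT3G20362 and AT1G72645 left out before scaling. The share of higher calls moved from 61.2% to 6.84% with total scaling. The RUBY level reversed to -0.045 with total scaling and lay between 0.63 and 1.14 without either always red library. It was past the threshold under no setting run. With an estimated correlation 0 lists passed, against 3 higher and 2 lower, and with each position and length counted once 1 list was lower. Reversed without being past the threshold were AT2G07732 (0.53, each position and length once), the circadian clock list (median -0.12, test direction up, all transcripts summed) and the flowering markers (median -1.08, test direction up, total scaling). The RUBY distance of 11.8 became 5.60 with each position and length counted once and lay between 11.7 and 12.0 without either always red library. The 9 RUBY codons became 47 at 5 times the mean and 2 at 20 times, while counting each position and length once could give no such codon. Frame 0 of fully red 1 moved from 26.1% to 25.3% without coding ends, 37.5% without AT3G20362 and 36.7% when distinct as well, and the always red mean from 38.9% to 38.2%, 42.1% and 40.8%. The 5′ share of fully red 1 over the always red mean moved from 1.12 to 1.04 with 1 read length, 1.89 without AT3G20362 and 1.64 with distinct footprints, and lay between 1.1 and 1.14 without either always red library. The 3′ ratio moved from 0.47 to 0.46 with transcript number 1 of each gene, 0.39 with 1 read length, 0.79 without AT3G20362 and 0.86 with distinct footprints, between 0.465 and 0.469 without either always red library. Apart from those where an alternative's own construction shows it, the cause was not tested.

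Of the 51 named genes past the threshold, all kept their sign wherever they could be tested. 24 of 45 stayed past it with each position and length counted once, 44 of 51 with median-of-ratios factors and 0 of 33 among genes with 100 or more P-sites. Some of the named results passed only under an alternative. Lower in fully red 1 were 4 genes and the glucosinolate list with total scaling, 1 gene with 1 read length and, with all transcripts summed, the list of RNA silencing and DNA methylation (median -0.56, adjusted p 0.031, against 0.126). Leaving out an always red library left 1 against 1, a value with no test. No paired analysis was possible because the labels give no replicate numbers and the events share none. Chloroplast and mitochondrial identifiers had no lines, so leaving them out gave no value. Whether organellar reads lay on nuclear identifiers was not tested. A count test with DESeq2, planned only for files with a column of counts, was not run. Depth was limited by the 339147 distinct footprints of fully red 1, and that library has no replicate to leave out.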

Other observations

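All values in this part were examined after the results were seen. Footprints of fully red 1 lay nearer the 5′ end of coding sequences. Over endogenous genes of at least 100 codons, by distinct footprints, the first of 10 equal parts held 12.7% and 12.1% in the always red libraries and 17.2% in fully red 1. The first 15 codons held 7.60%, 7.40% and 10.1% of coding P-sites without AT3G20362. In RUBY that part held 11.3%, 12.4% and 12.7% of distinct footprints. It spans positions 17 to 412 there, so a rise limited to the first codons could be missed.

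Among clock genes the always red libraries stood further apart, at a median absolute log2 difference of 1.83 over 15 genes, than fully red 1 did from always red 2 (0.36). MT3 (AT3G15353), chosen after its values were seen, had 14027 reads on 90 distinct footprints in the 5′ untranslated region in fully red 1, against 405 reads on 77 and 315 on 65 in the always red libraries. A second gene, AT1G72645, had 58.8% of its P-sites at a single position in fully red 1.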
